A study of Mus musculus with 8 samples.

How the data were processed

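RNA from adult mouse testis was sequenced in 8 libraries, 4 labelled Ak9 knockout and 4 labelled wild type. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase and made into libraries with an Illumina TruSeq RNA kit. The values used are the raw counts per Ensembl gene that the authors deposited, whole numbers with no normalization. Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and DESeq2 were used with the mouse builds GRCm39 and mm39. Their versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads of a gene and of an overlapping gene on the other strand are therefore not told apart here.

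The count table had 56748 gene identifiers, of which 52073 were matched to a symbol and 4675 were not. The unmatched identifiers held 0.411% to 1.07% of a library's counts. No column was left without a sample (0 unmapped columns). Totals ran from 18062780 to 24415587 counts per library. A count of 0 allows a level of up to 0.123 to 0.166 CPM (counts scaled to a common library total), taking 3 counts as the 95% limit. This limit covers counting error only and is per total count of the library, without the TMM scaling described below. Neither the labels nor the design text say whether the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. No library was a copy of another: the chi-square per gene between libraries of a group was 4.19 or higher.

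Low counts were removed with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 21805 genes. Libraries were scaled by TMM and the groups compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2, labelled knockout over wild type, and each standard error (SE) is the size of the log2 fold change divided by the square root of F. CPM in the text are TMM-scaled, per total count of the tested genes in the library. For Ak9, an exact permutation test of the CPM was added.

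The 25 gene lists, fixed before the data were examined, cover adenylate and nucleoside kinases, glycolysis, oxidative phosphorylation, cholesterol synthesis, the sperm axoneme, fibrous sheath and outer dense fibres, sperm ion transport and cAMP signalling, spermiogenesis regulators, the piRNA pathway, spermatogonia, spermatocytes, round and elongating spermatids, Sertoli, Leydig, peritubular myoid and stromal, endothelial, macrophage, blood and epididymis markers, immediate early and heat shock genes, p53 targets, interferon response, mitochondrially encoded genes and cytosolic ribosomal proteins. Each was tested with camera on log-CPM values with a preset correlation of 0.01, adjusted over the 25 lists. A list score is the mean log2 CPM of its tested genes in a library minus the wild-type mean.

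The genes named in the text follow a rule fixed with the lists. It takes Ak9 and the other adenylate kinase genes, then the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with at least 1 CPM, no overlap between groups and a symbol that is not a predicted or clone name. Where fewer pass, the genes with the next smallest p fill up to 5 per direction, under the same conditions of level, overlap and symbol. These are said not to have passed. From each list the rule takes up to 3 members past the threshold or, with none, the member with the smallest p. Gm7435 and Gm49725 fall outside this rule, as do the other genes named in the closing section and the further list members given as examples. These were chosen after their values were seen. Some genes that the rule takes are not reported here.

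Alternatives were the replicate number as a block, RLE size factors, no low-count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with and without sample quality weights, a 1.5-fold minimum, leaving out mitochondrially encoded genes, leaving out each library in turn, and for lists an estimated correlation and fry. Camera on counts, and an estimated correlation with labelled knockout 3 left out, were added after the data were examined. Near-identical copies were sought with blastn 2.17.0 among GENCODE M21 transcripts, at 95% identity over 80% of the length. That annotation is on GRCm38, not the authors' build, so it was used for names, gene order, overlaps and chromosomes only and no coordinates are given.

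Genes high in some labelled knockouts and low in others were those with a mean of at least 1 CPM, a gap of at least 2 in log2(CPM + 0.5) among the 4 labelled knockouts and a wild-type range of at most 1. In simulated counts, 46 of 50 genes made 16-fold higher in 3 of the 4 libraries were found.

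The scripts were tested on simulated counts for the comparison of labelled knockout with wild type over 21805 genes, with 50 genes changed at each fold size. edgeR recovered 12% of the genes changed 1.5-fold, 62% at 2-fold, 92% at 4-fold and 92% at 8-fold, with 8 false calls, and made 1 call in data with no change. Camera called a simulated list lowered by 0.50 on the log2 scale and 0 others. The simulated genes varied independently, whereas the estimated correlation within the Leydig list was 0.33 in the data. The simulation therefore cannot show how often camera with the preset correlation calls lists wrongly here. DESeq2 recovered 22%, 72%, 96% and 96% at the same sizes, with 31 false calls, and made 8 calls with no change.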

Results

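Gene expression was measured by RNA sequencing in adult mouse testis, in 4 libraries labelled Ak9 knockout and 4 labelled wild type. AK9 is an adenylate kinase, an enzyme family that interconverts adenine nucleotides, and the series concerns its part in male fertility and sperm motility. Total counts were 23846772, 20801729, 18062780 and 19023732 in labelled knockouts 1 to 4 and 18763650, 21485886, 24415587 and 19945942 in wild types 1 to 4. The libraries labelled knockout differed more among themselves than the wild types did. Their pairwise Spearman correlations across genes were 0.957 to 0.977, against 0.991 to 0.993 among wild types, and the median SD of log2 CPM was 0.33 against 0.14.

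The first comparison asked whether the targeted gene itself was lower. Ak9 (ENSMUSG00000091415) stood at 69.3, 116, 101 and 40.6 CPM in labelled knockouts 1 to 4 and at 108, 115, 122 and 107 CPM in wild types 1 to 4. The levels in the libraries labelled knockout were 61.5%, 103%, 89.4% and 36.0% of the wild-type mean, from 1538, 2403, 2043 and 697 counts. Ak9 was below every wild type in labelled knockouts 1, 3 and 4, and labelled knockout 2 lay within the wild-type range. The place of labelled knockout 3 rests on the TMM scaling, since its 2043 counts exceeded the 2019 of wild type 1 from a smaller library total. The difference did not pass the test (log2 fold change -0.47, SE 0.25, n = 4 per group, edgeR adjusted p = 1.00, two-sided exact permutation p = 0.143, where the smallest possible is 0.0286). Gene totals cover all exons together, and which part of the gene was targeted is not given in the sources used here. Because Ak9 transcript levels did not follow the labels in each library, every direction given here is between libraries labelled knockout and libraries labelled wild type.

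Other adenylate kinase genes showed no difference past the threshold. The log2 fold changes were 0.06 for Ak1, -0.03 for Ak3, -0.10 for Ak4, 0.27 for Ak5, 0.05 for Ak6, 0.04 for Ak7 and 0.10 for Ak8 (SE 0.10 to 0.24). The testis-rich members Ak1, Ak7 and Ak8 had wild-type means of 189 ± 16.8, 89.1 ± 5.85 and 225 ± 17.0 CPM (SD, n = 4). The list of adenylate and nucleoside kinases as a whole did not pass (camera adjusted p = 0.820). Its median log2 fold change was 0.03 and its mean -0.02, with the test pointing up. Its member with the smallest p was Nme2, a nucleoside diphosphate kinase, at 1.42 ± 0.415 CPM in libraries labelled knockout and 2.05 ± 0.535 in wild types (log2 fold change -0.53, SE 0.28).

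Across the testis, 4 genes passed edgeR's test as higher in the libraries labelled knockout and none passed as lower. Rps26-ps1 (ENSMUSG00000059775), a pseudogene of the ribosomal protein gene Rps26, rose from 0.663 ± 0.0962 to 12.2 ± 0.888 CPM (SD, n = 4 per group). Gm7435 (ENSMUSG00000111662), another processed pseudogene, rose from 1.64 ± 0.154 to 23.8 ± 4.88 CPM. Slc26a10 (ENSMUSG00000040441), of a family of anion transporters, rose from 4.38 ± 0.704 to 20.1 ± 3.58 CPM. Gm49725 (ENSMUSG00000116576), a long noncoding RNA, rose from 4.81 ± 0.677 to 16.4 ± 3.36 CPM.

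In edgeR's quasi-likelihood test the log2 fold changes were 4.19 for Rps26-ps1 (SE 0.19, adjusted p = 2.88e-06), 3.85 for Gm7435 (SE 0.20, adjusted p = 6.52e-06), 2.20 for Slc26a10 (SE 0.18, adjusted p = 0.000743) and 1.76 for Gm49725 (SE 0.18, adjusted p = 0.00520). All 4 labelled knockouts exceeded all 4 wild types for each of them. In GENCODE M21 (GRCm38) they lie on chromosomes 8, 9, 10 and 16 in that order, and Ak9 lies on chromosome 10. Rps26-ps1 is 99.1% identical to Rps26 and Gm7435 is 95.8% identical to Gm7444, so reads of either pair could be counted for the other. Rps26-ps1 also overlaps Wwp2, and Slc26a10 overlaps B4galnt1, each on the other strand. Wwp2 had 168 ± 35.9 CPM in libraries labelled knockout and 168 ± 14.2 in wild types, and B4galnt1 33.6 ± 3.35 and 32.9 ± 2.59. Rps26 stood at 157 ± 22.6 CPM in libraries labelled knockout and 179 ± 3.91 in wild types, and Gm7444 at 386 ± 145.0 and 432 ± 8.12. The adjusted p of Gm49725 was 0.0868 with the replicate block and 0.0610 without wild type 1.

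**Figure D1:**
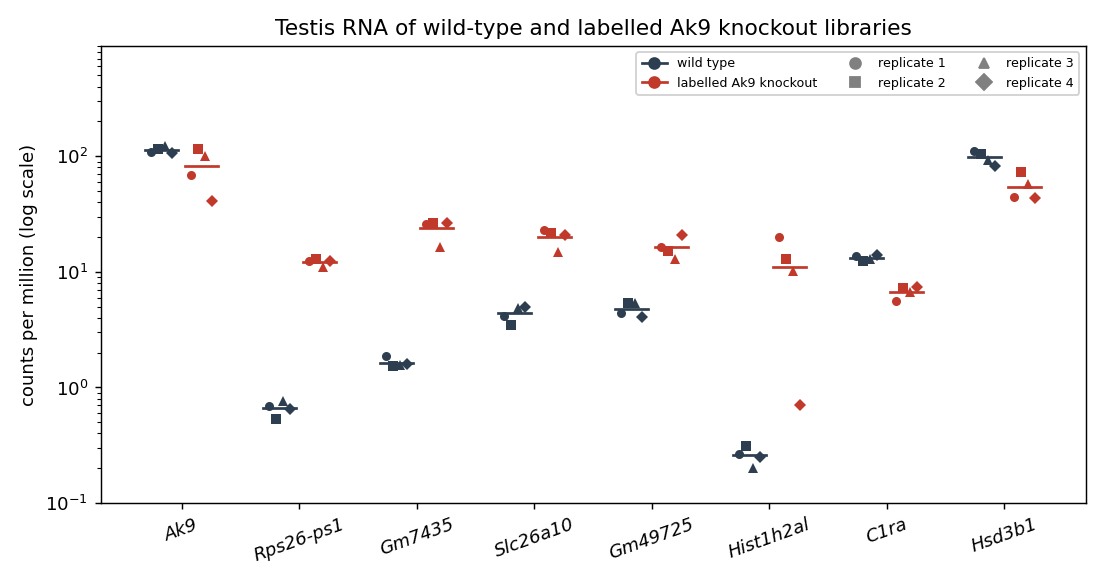
CPM of 8 genes on a log axis in the 4 wild-type libraries (dark) and the 4 libraries labelled Ak9 knockout (red), with 1 point per library, marker shape for the replicate number and a bar at each mean. Rps26-ps1, Gm7435, Slc26a10 and Gm49725 passed edgeR's test, and Ak9, Hist1h2al, C1ra and Hsd3b1 did not, of which DESeq2 called Hist1h2al, C1ra and Hsd3b1.

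The next genes on the higher side did not pass edgeR's test, and DESeq2 called them (DESeq2 adjusted p = 3.38e-06 for Hist1h2al, 2.64e-05 for Stat2 and 0.0260 for Jam2). Hist1h2al, annotated in GENCODE M21 as a processed pseudogene and named after the histone H2A family, was at 19.8, 13.0 and 10.3 CPM in labelled knockouts 1 to 3, at 0.700 in labelled knockout 4 and at 0.258 ± 0.0463 in wild types (log2 fold change 5.38, SE 0.83, edgeR adjusted p = 0.0970). Stat2, a transcription factor of interferon signalling, had 16.9 ± 1.70 against 9.53 ± 1.03 CPM (log2 fold change 0.83, SE 0.14, edgeR adjusted p = 0.137). Jam2, a junctional adhesion molecule, had 38.9 ± 2.90 against 28.5 ± 0.951 CPM (log2 fold change 0.45, SE 0.10, edgeR adjusted p = 0.495).

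On the lower side the smallest edgeR adjusted p was 0.0867, for the complement gene C1ra, at 6.72 ± 0.825 CPM in libraries labelled knockout and 13.2 ± 0.661 in wild types (log2 fold change -0.98, SE 0.14). Its close copy C1rb, which could share reads with it, was at 6.81, 8.88, 9.97 and 0.350 CPM in labelled knockouts 1 to 4 and at 0.254 on average in wild types. C1ra was at 5.54, 7.24, 6.76 and 7.35 CPM in the same 4 libraries, so it was lower in labelled knockout 4 without a higher C1rb there. Mybpc1, a myosin-binding protein, had 2.25 ± 0.502 against 6.24 ± 1.19 CPM (log2 fold change -1.47, SE 0.22). Fetub, a secreted protease inhibitor, had 1.52 ± 0.395 against 4.40 ± 0.779 CPM (log2 fold change -1.54, SE 0.24). A1cf, an RNA-binding protein, had 2.73 ± 0.739 against 7.04 ± 1.19 CPM, and Aig1 had 2.14 ± 0.377 against 4.66 ± 0.0602 CPM. Their log2 fold changes were -1.36 (SE 0.22) and -1.11 (SE 0.19). The naming rule took only genes in which every labelled knockout lay below every wild type, so that separation was set by the choice. DESeq2 called all 5 of these genes (DESeq2 adjusted p from 2.26e-07 for C1ra to 0.000241 for Aig1).

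Of 21805 genes tested with edgeR, 4 were higher and 0 lower at an adjusted p under 0.05, and 272 were higher and 390 lower at an unadjusted p under 0.05. limma-voom also called 4 higher and 0 lower, and DESeq2 called 27 higher and 21 lower. The groups did not overlap for 501 genes, 2.30% of those tested, where chance gives 2.86%. The edgeR threshold was passed by 33 genes without labelled knockout 1 (9 higher and 24 lower), 35 without labelled knockout 3 (23 higher and 12 lower) and 33 without labelled knockout 4 (14 higher and 19 lower).

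Markers of Leydig cells, the steroid-producing cells between the tubules, had the smallest p of the 25 lists. All 14 were below 0 in log2 fold change, with a median of -0.31, and the list was lower (camera with preset correlation, adjusted p = 2.67e-09). The adjusted p = 0.617 with an estimated correlation. Hsd3b1, which makes progesterone and androstenedione, had 54.7 ± 13.7 CPM in libraries labelled knockout and 98.3 ± 12.8 in wild types (log2 fold change -0.85, SE 0.17). Hsd3b1 has close relatives whose reads the counting could split, among them Hsd3b6 at a log2 fold change of -0.24 (SE 0.21). Sult1e1, the oestrogen sulfotransferase, had 12.0 ± 7.96 against 30.8 ± 4.37 CPM (log2 fold change -1.37, SE 0.34). These 2 genes passed when adjusted over the list alone (edgeR adjusted p = 0.00541 and 0.0130), and 0 passed over all genes tested with edgeR, while DESeq2 called both over all genes (DESeq2 adjusted p = 0.00588 and 0.0304). Star, which delivers cholesterol to mitochondria, Cyp11a1, which starts steroid synthesis, and the peptide hormone Insl3 had log2 fold changes of -0.47 (SE 0.26), -0.37 (SE 0.22) and -0.32 (SE 0.17). The list score was -0.40, -0.46, -0.12 and -0.86 in labelled knockouts 1 to 4, below all wild types (exact permutation p = 0.0286, the smallest possible, and 0.357 adjusted over the 25 lists).

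**Figure D2:**
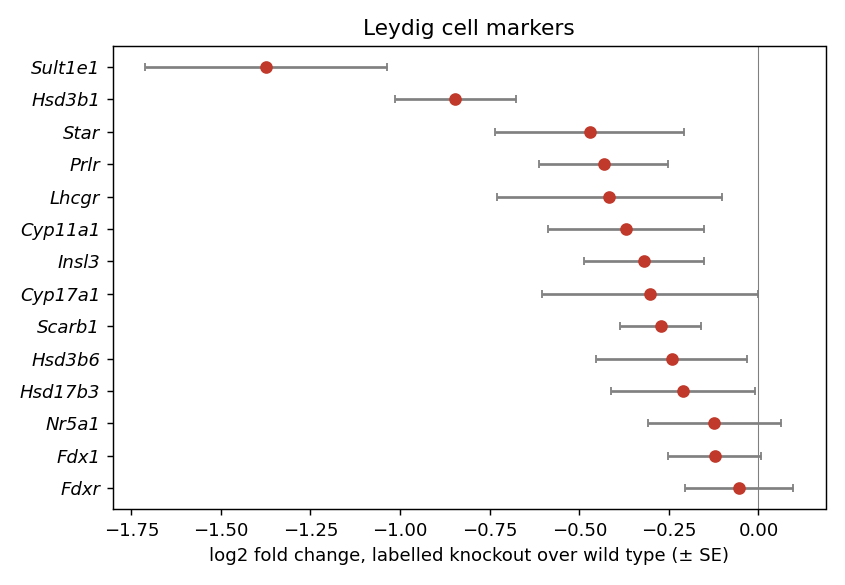
Log2 fold change of the 14 Leydig cell markers, libraries labelled Ak9 knockout over wild type, with points for edgeR estimates and bars of 1 SE on each side (n = 4 per group). All 14 lie below 0, from -1.37 for Sult1e1 to -0.05 for Fdxr.

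Cholesterol synthesis genes were also lower as a list (13 of 18 below 0, median -0.15, camera adjusted p = 0.0160, and adjusted p = 0.909 with an estimated correlation). No member passed alone. Dhcr7 and Lss had log2 fold changes of -0.38 (SE 0.21) and -0.32 (SE 0.18). Without labelled knockout 2 or 4 or wild type 1 or 3 the adjusted p was 0.117, 0.210, 0.0593 and 0.116.

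Genes of the sperm axoneme, the motor core of the tail, were higher as a list by a small amount (35 of 41 above 0, median 0.10, camera adjusted p = 0.00311, and adjusted p = 0.909 with an estimated correlation). No member passed. Cfap61, a radial spoke protein, had 79.2 ± 15.6 CPM in libraries labelled knockout and 57.7 ± 1.89 in wild types (log2 fold change 0.46, SE 0.14), and Dnah8 and Tekt1 had log2 fold changes of 0.31 (SE 0.20) and 0.25 (SE 0.15). The list score was 0.23, 0.01, -0.18 and 0.24 in labelled knockouts 1 to 4, and without labelled knockout 1 or 4 the adjusted p was 0.421 and 0.392. Spermatid scores ran alike in these libraries, at 0.36, 0.24, -0.65 and 0.29 for round and 0.37, 0.10, -0.84 and 0.43 for elongating spermatids.

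The other germ cell lists did not pass. Round spermatid genes had a median of 0.12 (14 of 14 above 0, camera adjusted p = 0.283), with Tex36 at 120 ± 43.1 against 102 ± 10.6 CPM. Elongating spermatid genes had a median of 0.09 (adjusted p = 0.611), with the kinase gene Tssk3 at 166 ± 51.7 against 145 ± 19.6 CPM. Labelled knockout 3 stood apart in both, with scores of -0.65 and -0.84, while the other labelled knockouts lay between 0.24 and 0.36 and between 0.10 and 0.43. Fibrous sheath and outer dense fibre genes (median 0.09, adjusted p = 0.297, Odf4 log2 fold change 0.18, SE 0.13) and sperm ion transport and cAMP signalling genes (median 0.06, adjusted p = 0.616, Prkaca 0.11, SE 0.11) had scores of -0.59 and -0.40 in that library. Spermiogenesis regulators (median 0.07, adjusted p = 0.384, Mybl1 0.18, SE 0.10), spermatocyte genes (median 0.03, adjusted p = 0.317, Syce3 0.22, SE 0.14) and piRNA pathway genes (median 0.05, adjusted p = 0.0977, Tdrd7 0.18, SE 0.13) did not pass. The piRNA score was 0.04, 0.06, 0.07 and 0.05 in labelled knockouts 1 to 4 and at most 0.03 in wild types, with the same exact permutation p of 0.0286 and adjusted p of 0.357. Spermatogonial genes had a median of -0.12 (adjusted p = 0.0830), with Ret, a receptor of stem spermatogonia, at -0.31 (SE 0.22). Without labelled knockout 3, 13 of the 25 lists passed with the preset correlation, among them round and elongating spermatids higher and Sertoli cells and spermatogonia lower. With correlations estimated from the same 7 libraries 0 lists passed, and the smallest adjusted p was 0.391.

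**Figure D3:**
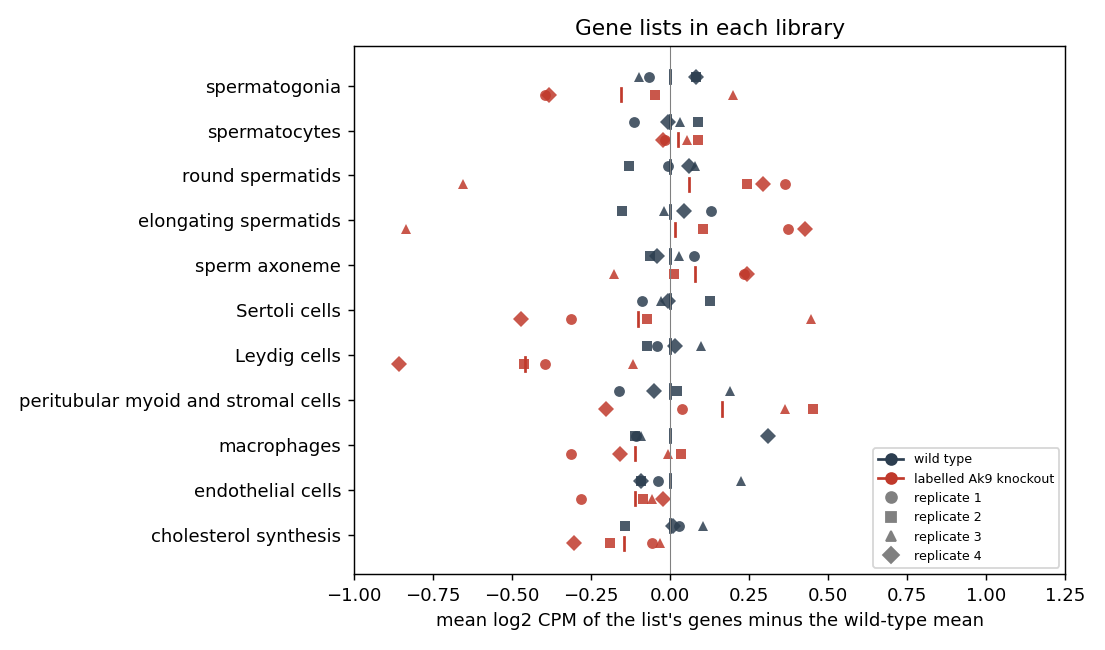
Mean log2 CPM of the genes of 11 lists in each library, minus the wild-type mean, for wild types (dark) and libraries labelled Ak9 knockout (red), with marker shape for the replicate number and a bar at each group mean. All 4 labelled knockouts lie below the wild types for Leydig cells, and labelled knockout 3 lies at -0.84 for elongating spermatids and 0.45 for Sertoli cells.

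Among the other somatic cells, peritubular myoid and stromal genes were higher as a list (10 of 12 above 0, median 0.24, camera adjusted p = 0.0160, and adjusted p = 0.909 with an estimated correlation). Acta2, smooth muscle actin, had 69.1 ± 17.8 against 54.8 ± 6.14 CPM (log2 fold change 0.34, SE 0.18), with no member past the threshold. Without labelled knockout 2 or 3 or wild type 1 the adjusted p was 0.379, 0.323 and 0.137. Sertoli cell genes did not pass as a list (median -0.04, adjusted p = 0.297). Of these, 2 passed when adjusted over the list alone and 0 over all genes, in opposite directions: Kitl, which supports germ cells, at 24.9 ± 4.10 against 35.2 ± 4.04 CPM (log2 fold change -0.50, SE 0.13), and Sox9, a Sertoli transcription factor, at 0.48 (SE 0.13). Sertoli scores were -0.31, -0.07, 0.45 and -0.47 in labelled knockouts 1 to 4. Endothelial (median -0.10, adjusted p = 0.297, Kdr -0.36, SE 0.20) and macrophage genes (median -0.08, adjusted p = 0.279, Lyz2 -0.28, SE 0.15) did not pass.

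Energy pathways showed no difference past the threshold in all 8 libraries. Without labelled knockout 3, glycolysis and oxidative phosphorylation passed as higher with the preset correlation (camera adjusted p = 0.0475 and 0.0459) and not with an estimated one (0.657 and 0.560). Over all 8 libraries, glycolysis genes had a median and a mean of 0.01 with the test pointing down (adjusted p = 0.836), and Pgk1 was at 23.8 ± 2.52 against 26.2 ± 0.556 CPM. Oxidative phosphorylation genes had a median of 0.04 (adjusted p = 0.283), with the testis cytochrome c gene Cyct at 0.18 (SE 0.11). Mitochondrially encoded genes had a median of -0.02 (adjusted p = 0.820), with mt-Atp6 at 4.47 ± 1.14 against 6.24 ± 0.314 CPM, and cytosolic ribosomal protein genes 0.06 (adjusted p = 0.297, Rps6 0.19, SE 0.14).

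Stress and response lists did not pass either in all 8 libraries. Immediate early and heat shock genes had a median of 0.07 (adjusted p = 0.738, Egr1 -0.40, SE 0.38), p53 targets and apoptosis genes -0.06 (adjusted p = 0.408, Pmaip1 -0.32, SE 0.22) and interferon response genes 0.05 (adjusted p = 0.297, Rtp4 0.75, SE 0.36). With the preset correlation, the p53 list passed as lower without labelled knockout 3 (camera adjusted p = 0.0286), but not with an estimated one (0.560). The interferon list passed as higher with the preset correlation without labelled knockout 4 (0.0165) or wild type 3 (0.0247). The blood list had a median of 0.10 and a mean of -0.09 with the test pointing down (4 genes tested, adjusted p = 0.905, Slc4a1 -0.83, SE 0.32). The epididymis list had a median of -0.04 and a mean of 0.00 with the test pointing down (3 genes tested, adjusted p = 0.611, Rnase10 -0.30, SE 0.26). Of the 8 epididymis genes below the count filter, 4 were at least 4-fold above every wild type in labelled knockout 3, and Gpx5 and Cst11 had 0 CPM there. Crisp1, a sperm-coating protein of the epididymis, was at 185 CPM in labelled knockout 3, 24.4 in labelled knockout 4 and at most 0.534 in the other libraries.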

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

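The tests of copies, of an effect in cis on Gm7435 and Gm49725, of reads moved between a gene and its copy, of depth, of the Leydig cell share and of epididymal tissue were chosen after the result was seen. The test of DESeq2 calls per chromosome was not set beforehand either.

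For the number of genes higher in the libraries labelled knockout, the real grouping gave 4 genes and the highest of the other 34 groupings gave 1. Of the 35 splits of the 8 libraries 1, the real one, gave as many, which is the smallest share the splits can give. The other splits mix the more variable labelled knockouts with wild types, which makes calls harder there. Chance is therefore not excluded by this test. Of the 40 tested genes nearest to Ak9 0 were called (one-sided Fisher exact p = 1), but with 4 calls in all only 0.00734 were expected there, so this decides nothing. Sequence linked to the targeted locus stays open for Slc26a10 and, through its copy Rps26, for Rps26-ps1. Slc26a10 and Rps26 lie on chromosome 10 of GENCODE M21 (GRCm38) with Ak9. A shared chromosome does not show close linkage, and Slc26a10 was not among the 40 tested genes nearest to Ak9. Of those 40 genes, 0 had an unadjusted p under 0.05 in edgeR's test, against 3.04% of the other tested genes. Of Gm7435 and Gm49725, 0 lie on chromosome 10 or have an annotated copy there, which argues against an effect in cis on these 2. Both Rps26-ps1 and Gm7435, 2 genes, have an annotated copy, so reads shared with Rps26 and Gm7444 may enter their counts, for example through variants that differ from the reference, whereas 0 of Slc26a10 and Gm49725 have one. A response to loss of AK9 stays open for all 4, and Ak9 itself did not follow the labels in each library. The labels name the genotype and give no strain, so a difference in strain background between the groups cannot be told apart from it. Chromosomes 10 and 16, which carry Slc26a10 and Gm49725, held more DESeq2 calls than their share of tested genes.

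A second pattern was found in genes high in some labelled knockouts and at least 4-fold lower in the others: 166 of 19426 genes, against 0 among wild types with the groups exchanged. The exchanged rule needs flat levels in the more variable labelled knockouts and is harder to pass, so the counts are not on equal terms. Neighbouring genes with the gap among labelled knockouts had the same pattern of high libraries in 56.6% of pairs, against 12.1% for permuted patterns (p = 1e-04, the smallest 10000 permutations can give). The share was 26.1% against 11.2% (permutation p = 0.006) over pairs more than 5 genes apart without chromosome 14 and without the genes high in labelled knockout 3 alone. Alleles of another strain segregating among the animals are therefore a candidate explanation. Reads moved between a gene and a near-identical copy may add to the pattern. Over 57 copies the parent's change ran against the copy's (Spearman rho = -0.31, permutation p = 0.0022, permuted median -0.15), with a negative correlation within 38 of the 57 pairs. Several copies shared a parent gene while libraries were permuted separately within each pair, so this p may be too small. A gene that itself had the gap could not serve as parent, so the dynein light chain genes Dynlt1a and Dynlt1b were not compared with each other. In only 20.5% of the genes did every low library have a smaller total than every high one (binomial 95% limits 14.6% to 27.4%), which argues against depth. These limits count the genes as independent, although neighbouring genes shared patterns, so they may be too narrow. For the 17 genes high in labelled knockout 3 alone, epididymal tissue was tested with the fixed marker list: 4 of 11 markers (Crisp1, Adam7, Rnase9 and Lcn5) were at least 4-fold above every wild type. Another 3 (Cst8, Rnase10 and Ros1) are expressed in the wild types already and could not show a small share. The remaining 4 were near 0, with Gpx5 and Cst11 at 0 CPM (which allows up to 0.166 before TMM scaling), so epididymal tissue stays open.

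A single library does not carry the third pattern, the lower Leydig cell markers: without labelled knockout 4, which had the lowest score, the camera adjusted p with preset correlation was 3.99e-05. A smaller share of Leydig cells would lower the markers alike, but 2 of the 14 (Fdx1 and Fdxr) separated the groups relative to the other markers, a number that 3 of the 35 splits reached (share 0.0857, highest other 2). Sult1e1 and Hsd3b1 departed further (-1.16 and -0.44) without separating the groups, and 5 of the 35 splits reached the SD of the 14 changes of 0.37 (median of the splits 0.23), so a smaller share stays open. For the number of lists past the threshold chance cannot be excluded: 29 of the 35 splits gave at least the real 4 lists and the highest gave 17, which points to a structure of the samples that the groups do not describe. A change within Leydig cells stays open as the biological explanation, and the list's call is lost with an estimated correlation (adjusted p = 0.617).

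Single libraries far from the others of their group were found in 13 of 152 sets of 4 values, where chance gives about 7.60. In labelled knockout 3, the adenylate kinase list score was -0.24, the round spermatid score -0.65, Gm7435 16.5 CPM and the share of counts in the top 10 genes 2.89%. Labelled knockout 1 had Rps6 at 182 CPM. Wild type 4 had 3.65% of counts in the top 10 genes, 1.07% in identifiers without a symbol, Lyz2 at 32.1 CPM and a macrophage score of 0.31. Wild type 2 had Stat2 at 7.99 CPM and a fibrous sheath score of -0.11, wild type 3 an endothelial score of 0.22 and wild type 1 a mitochondrially encoded score of -0.17.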

How the results depend on the processing

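The direction and the call of Rps26-ps1, Gm7435 and Slc26a10 were kept under every alternative, and Ak9 stayed lower and short of the threshold in all 15. Gm49725 missed the threshold with the replicate block (adjusted p = 0.0868) and without wild type 1 (0.0610). The number of genes past the threshold, 4 in the main test, was 48 with DESeq2, 14 with limma-voom and quality weights, 26 without a low-count filter and 3 to 35 when a library was left out, with 33, 35 and 33 without labelled knockouts 1, 3 and 4. The cause was not tested. All 4 genes were among the calls in each of these, apart from 3 of them without wild type 1. The number of lists, 4 in the main test, was 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and labelled knockout 3 left out, and 2 to 13 when a library was left out, with 2 without labelled knockout 2 or wild type 1 and 13 without labelled knockout 3. The list of glycolysis genes reversed without labelled knockout 3 (adjusted p = 0.0475, higher, in a range of 0.0475 to 0.947 over left-out libraries), where the cause was not tested. The Leydig list stayed lower with a preset correlation in every fit, with adjusted p from 6.51e-12 to 3.99e-05. Over all alternatives, values of single named genes stayed on their side of the threshold in 638 cases, newly passed in 28, missed it in 2 and moved by more than the spread in 5, and those of single lists stayed in 365, newly passed in 13 and missed it in 21.

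Replicate numbers did not clearly pair the libraries. Same-numbered libraries had correlations of 0.090, 0.044, -0.026 and 0.031 in their deviations from the group means. The mean correlations with the other numbers were -0.033, -0.012, 0.012 and -0.014. Of 4 labelled knockouts, 2 correlated best with their own number, and so few values cannot exclude a pairing. With the replicate block 4 genes passed, 3 of them shared with the main test. At this depth edgeR recovered 12% of simulated 1.5-fold changes and 62% of 2-fold changes, so smaller differences were mostly not detectable.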

Other observations

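Several genes had counts in all wild types and almost none in some libraries labelled knockout. The zinc finger gene Zfp990 was at 0.406 CPM in labelled knockout 1 and at 29.2 to 38.4 in the other labelled knockouts, with 33.5 ± 2.22 in wild types (SD, n = 4). Dynlt1b, a dynein light chain gene, was at 1.13 and 1.17 CPM in labelled knockouts 1 and 4 and at 90.9 and 115 in labelled knockouts 2 and 3, with 79.1 ± 5.46 in wild types. Its relative Dynlt1a was at 206, 118, 23.5 and 220 CPM in labelled knockouts 1 to 4, against 104 on average in wild types. Dynlt1a thus ran the other way in labelled knockouts 1, 3 and 4, so reads may have moved between these genes. The imprinted noncoding RNA Meg3 split labelled knockouts 1 and 4 from 2 and 3, at 1.31 and 1.34 against 15.3 and 14.5 CPM. Pnp2, a purine nucleoside phosphorylase gene, had 0 CPM in labelled knockout 1 and 14.04, 8.14 and 14.1 in the others. Of the 166 genes with such a gap, 163 had a place in GENCODE M21, among them 77 protein-coding genes and 40 pseudogenes. The most frequent set was high in labelled knockouts 2, 3 and 4 (40 genes), of which 18 lie on chromosome 14 of GENCODE M21 (GRCm38).

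Of the genes with such a gap, 17 were high in labelled knockout 3 alone, and the examples here were chosen after their values were seen. Cuzd1 was at 69.5 CPM there, 17.0 in labelled knockout 4 and 4.95 on average in wild types. The protease inhibitor gene Spink8 was at 50.6, 9.21 and 1.55 CPM in the same order. Ltf, which encodes lactoferrin, was at 15.7, 0.525 and 0.0226 CPM, and the defensin gene Defb28 at 14.01, 1.75 and 0.127. The keratin gene Krt18 was at 3.90, 0.233 and 0.454 CPM, and Cd52, of a cell surface glycoprotein, at 28.7, 4.02 and 0.834. Among the fixed epididymis markers, Adam7 was at 26.2 CPM in labelled knockout 3 and 4.20 in labelled knockout 4, against at most 0.180 in wild types.

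The 42 DESeq2 calls with a place in GENCODE M21 (GRCm38) that edgeR also tested were not spread evenly over chromosomes. Chromosome 16, with 3.02% of tested genes, held 7 of them, 16.7% (one-sided Fisher exact p = 0.000238, adjusted over the 17 chromosomes with a call 0.00405), including Gm49725, Jam2, Fetub, Cyyr1 and Adgrg7. Chromosome 10, which carries Ak9 and 4.998% of tested genes, held 8, 19.05% (Fisher exact p = 0.000982, adjusted 0.00834), including Slc26a10, Stat2, Mybpc1, Aig1, Stab2 and Syn3. Across all genes, the SD of log2 CPM was larger among libraries labelled knockout than among wild types for 84.9% of genes.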
